A study of Homo sapiens with 3 samples.

How the data were processed

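Single cells of the human embryonic stem cell line H9 were profiled by inDrop with the TruDrop protocol, a droplet method in which each cell receives a barcode and each captured RNA molecule a unique molecular identifier (UMI), per the labels' protocols. The labels give 3 libraries, 1 each for day 0, day 2 and day 6 of differentiation towards neural progenitor cells with a commercial SMAD inhibitor induction kit. The letters A, B and A that follow the days in the labels are not explained in the sources used here.

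For each library the authors deposited a matrix of whole-number counts per gene and barcode, with a list of barcodes and a list of gene symbols. The values were taken as UMI counts because the method uses UMIs; that duplicate reads were collapsed is not stated by the labels or the file headers. Alignment with STAR to hg38 is named in the submitters' processing notes, with no version. The annotation, the barcode filter and the strand setting are not given in the sources used here. Every barcode in the files had at least 100 genes, so a filter on genes had been applied before deposit.

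The 3 gene lists were joined by symbol into 31113 symbols. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 25% of UMIs from mitochondrially encoded genes. The UMIs of a gene were summed over the kept cells of a library and given as counts per 1000000 summed UMIs (CPM). Libraries were compared by the ratio of CPM with an exact conditional binomial 95% interval, single levels have exact Poisson 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. With 1 library per day there is no test between days and no check against replicates. All intervals cover counting error only and leave out the variation between cultures. A ratio against 0 UMIs is a lower bound computed with 3 UMIs in place of 0.

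The named genes of each comparison are the 10 highest and 10 lowest by the bound of the interval nearest to 1, among genes with at least 50 CPM in at least 1 of the 2 libraries. To these come the 10 genes highest and the 10 lowest in the library labelled day 2 against both others, and a set of pluripotency, neural, cadherin, DNA methylation and signalling genes. The lists of genes, the rule for named genes, the filters and most alternatives were fixed before the data were examined. For 35 gene lists with 641 symbols, members with at least 10 CPM in at least 1 library were counted as at least 2-fold higher, at most 0.5 times, or between. Of these symbols 19 were matched by an older symbol and 9 were not found. The median log2 ratio of a list with at least 3 measured members was placed among 10000 random lists of the same size, each member drawn from the 100 genes nearest in mean CPM. Such a percentile describes these libraries and is not a test of the days. The median log2 ratio of all genes with at least 10 CPM was 0.01 for labelled day 2 over day 0, 0.12 for day 6 over day 2 and 0.12 for day 6 over day 0.

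For shares of cells with a UMI and for cell cycle phases, every kept cell was thinned to 1000 UMIs, which left out no kept cell. Clusters were made with scanpy 1.11.5 from all kept cells: scaling to 10000 UMIs, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 with igraph 0.11.9. A cluster was called by a cell type only if at least 3 markers fixed beforehand were at least 2-fold higher than in all other cells and present in at least 10% of its cells, and if that type had more such markers than any other. This threshold was chosen after seeing the data. In addition, no other type could have more markers among the 10 leading genes of the cluster. A cluster with median UMIs under 1/3 of the median of its main library also needed a marker of its type among these genes. Doublets were kept: the caller scrublet marked 3, 3 and 0 cells in the libraries labelled day 0, day 2 and day 6, too few for the caller to have worked. Removing the cells with scores above the 95th percentile of their library, called the highest 5% of scores here, was therefore added as an alternative after seeing the data; since tied scores at the limit were kept, it took out 107, 97 and 156 cells. Also added then were the restriction to cells with at least 5% mitochondrial UMIs and, for ratios, lists and counts of genes, leaving out the 2, 42 and 150 cells in clusters mostly of another library.

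Other scalings were TMM factors from edgeR 4.0.16, median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, and the mean of each cell's own CPM. The calculations of ratios, named genes and list medians were tested on simulated data made from the real totals, with 9541 genes in each comparison. Intervals held the true ratio for 95.6%, 95.6% and 95.4% of genes in the comparisons of labelled day 2 with day 0, day 6 with day 2 and day 6 with day 0. The simulated counts were Poisson draws without variation between cells, as the interval assumes, so this checks the calculation only. Gene positions are 1-based, on GRCh38 from GENCODE v29, and are given only for symbols found there; 21371 of the 31113 symbols were. The files use hg38, the same build, but may use another annotation release. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.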

Results

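The transcriptomes of single H9 cells, an established human embryonic stem cell line, were measured in 3 libraries labelled day 0, day 2 and day 6 of neural progenitor differentiation. The series title places the experiment in a study of DNA demethylation and enhancers during this differentiation. The files held 11291, 12323 and 16073 barcodes with 32831973, 32005289 and 51492505 UMIs. After filtering, 2290, 2419 and 4180 cells remained, with 28341741, 20626135 and 41268018 UMIs. The median UMIs per kept cell were 8770, 3814 and 4429, and the median genes per cell 3135, 1749 and 2071, in the same order. At these totals, 3 UMIs correspond to 0.106, 0.145 and 0.0727 CPM.

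The marker content of the libraries went against their day labels. The library labelled day 0 held 2.22 CPM (95% interval 1.71 to 2.84) of POU5F1, the pluripotency factor OCT4, whereas that labelled day 2 held 1229 CPM (1214 to 1244) and that labelled day 6 held 268 CPM (263.5 to 274). PAX6, a neural progenitor transcription factor, stood at 176 CPM (171 to 180), 6.64 CPM (5.58 to 7.85) and 27.9 CPM (26.3 to 29.6) in the same order. Part of the lower levels comes from a few cells: without the 42 cells labelled day 2 and 150 labelled day 6 that clustered mostly with another library, PAX6 stood at 4.12 and 21.2 CPM in those libraries. Not every neural gene had the order of PAX6. OTX2 stood at 86.1, 30.6 and 105 CPM in the libraries labelled day 0, day 2 and day 6. SOX1 was low in all of them, at 1.62, 0.921 and 4.85 CPM. POU5F1 lies on chromosome 6 at 31164337 to 31180731, and PAX6 on chromosome 11 at 31784779 to 31818062. Because the marker content went against the labels, the libraries are named by their labels throughout, and differences between them are not given as changes over time.

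**Figure D1:**
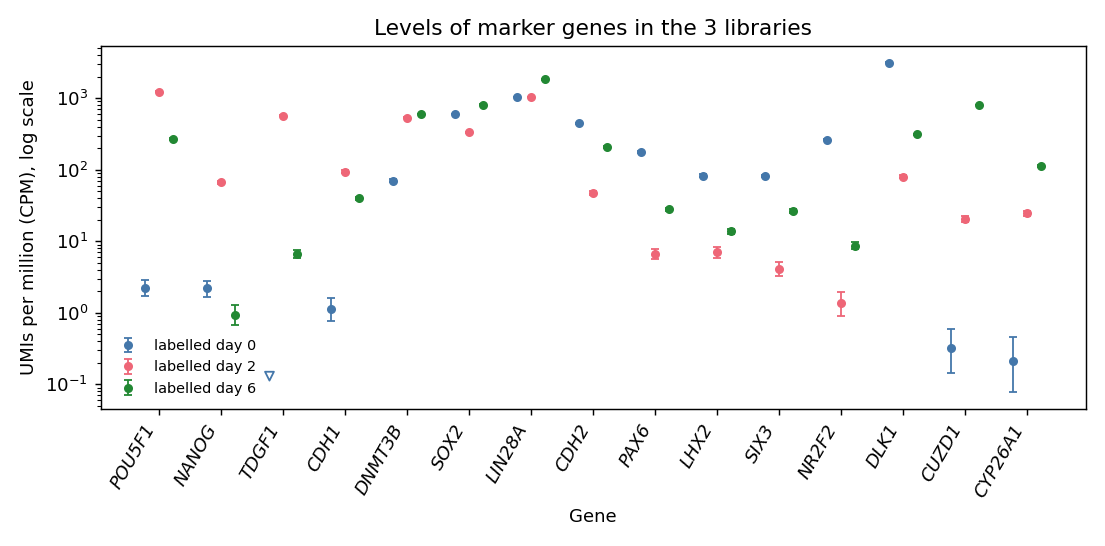
CPM on a log scale of 15 marker genes in the libraries labelled day 0, day 2 and day 6, with exact Poisson 95% intervals of counting error; the open triangle is the upper bound for TDGF1, which had 0 UMIs in the library labelled day 0. POU5F1 stands at 2.22, 1229 and 268 CPM, PAX6 at 176, 6.64 and 27.9 CPM.

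The first comparison asks how the libraries labelled day 2 and day 0 differ. Pluripotency genes were higher in the library labelled day 2, and neural progenitor genes in that labelled day 0. Of 17 measured core pluripotency genes 13 were at least 2-fold higher in the library labelled day 2 and 0 were at most 0.5 times, with a median log2 ratio of 2.91 (percentile 100 among random lists). Of 23 measured neural progenitor genes 19 were at most 0.5 times and 1, ZIC5, was at least 2-fold higher, with a median of -3.13 (percentile 0). In the forebrain and eye field list 8 of 9 members were at most 0.5 times, with a median of -3.77. TDGF1, a Nodal co-receptor on chromosome 3 at 46574534 to 46582463, had 0 UMIs in the library labelled day 0 and 569.5 CPM in that labelled day 2, at least 5380-fold higher. POU5F1 was 553-fold higher (432 to 720). The related POU5F1B was 241-fold higher (196 to 299); the sequences of these genes are nearly alike, so how their reads were divided is uncertain. ESRG, a non-coding RNA of pluripotent cells, was 1847-fold higher (937 to 4278). FOXD3-AS1, with 1 UMI in the library labelled day 0, was 3302-fold higher with an interval from 592; without a stated strand setting it cannot be separated from FOXD3. The other genes named at this end were the non-coding RNAs LINC00678, RP11-415G4.1, CTD-2142D14.1, RP11-256I9.2 and RP11-1144P22.1.

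Among the genes higher in the library labelled day 0, NR2F2, a nuclear receptor of early neural and mesenchymal tissue on chromosome 15 at 96325938 to 96340263, was 194-fold higher (134 to 293) than in that labelled day 2. DLK1, an imprinted gene for a Notch-related membrane protein, stood at 3137 and 79.5 CPM, a ratio of 39.5 (37.6 to 41.5). WLS, which carries WNT proteins to the cell surface, was 42.2-fold higher (34.4 to 52.3), and the homeobox gene MEIS2 31.8-fold higher (24.8 to 41.4). LIX1, ZNF503, GREB1L, GLIS3, PRTG and AC093590.1 made up the rest, between 27.7-fold (PRTG) and 201-fold (AC093590.1) higher. SIX3 stood at 82.2 CPM in the library labelled day 0 and 4.12 CPM in that labelled day 2, LHX2 at 82.4 and 6.98 CPM, and HES5 at 32.7 and 3.73 CPM. Without the 42 cells, the levels in the library labelled day 2 were 17.0 CPM for DLK1, 1.27 CPM for SIX3, 3.04 CPM for LHX2 and 0.833 CPM for HES5, so that DLK1 was 184-fold higher (166 to 206) in the library labelled day 0, and LIX1 went from 112-fold to 246-fold. Such cells were picked by their expression, so leaving them out widens differences in genes of these clusters by construction. The intervals, here and in the later comparisons, do not cover that choice. LIN28A, an RNA-binding protein of pluripotent and early neural cells, was at 1039 and 1037 CPM.

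The second comparison sets the library labelled day 6 against that labelled day 2. Here neural progenitor genes were higher and pluripotency genes lower in the library labelled day 6. Of the 23 neural progenitor genes 16 were at least 2-fold higher and 0 were at most 0.5 times, with a median log2 ratio of 1.74 (percentile 100). Of the 17 core pluripotency genes 9 were at most 0.5 times and 2, SOX2 and SALL4, at least 2-fold higher, with a median of -1.44 (percentile 0). SOX21, on chromosome 13 at 94709622 to 94712399, was 50.3-fold higher (38.3 to 67.45), and LHX5, a forebrain homeobox gene on chromosome 12 at 113462034 to 113472280, stood at 2.57 CPM in the library labelled day 2 and 129 CPM in that labelled day 6. LHX5-AS1, whose gene overlaps LHX5 on the other strand, was 38.8-fold higher (27.1 to 57.6) and may not be separable from it in these counts. CUZD1, a zona pellucida domain protein on chromosome 10 at 122832149 to 122850793, stood at 20.3 and 801.5 CPM, a ratio of 39.6 (35.9 to 43.7). Without the few cells that clustered with another library, LHX5 was 75.8-fold higher (54.4 to 109) and LHX5-AS1 68.7-fold (42.8 to 118). SHISA3, ZEB2, LIMCH1, GREB1L, RP11-82L7.4 and RP11-63A11.1 were the other genes named, between 18.9-fold (ZEB2) and 46.7-fold (RP11-82L7.4) higher. In the opposite direction, NANOG was 70.5-fold higher (51.3 to 99.6) in the library labelled day 2, TDGF1 85.2-fold (75.6 to 96.3) and LINC00678 171-fold (115 to 265). ANKRD31, RP11-174G6.1, FOXD3-AS1, RP11-415G4.1, AK4, CLDN7 and PMAIP1 followed, between 26.7-fold (PMAIP1) and 75.6-fold (ANKRD31).

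The third comparison, of the libraries labelled day 6 and day 0, spans the labelled time course. Pluripotency genes were higher in the library labelled day 6, and more of the neural progenitor genes were lower than higher. Of the core pluripotency genes 11 were at least 2-fold higher and 1, NANOG, was at most 0.5 times, with a median log2 ratio of 2.15 (percentile 100). Of the neural progenitor genes 12 were at most 0.5 times and 6 at least 2-fold higher, with a median of -1.07 (percentile 0); with a minimum of 50 CPM, 7 were at most 0.5 times and 6 at least 2-fold higher, with a median of -0.49. The members higher in the library labelled day 6 included FEZF1 (424 against 160 CPM) and HESX1 (99.3 against 16.3 CPM). Forebrain and eye field genes had a median of -1.65 over 9 members, which turned to 0.79 with the minimum of 50 CPM. CUZD1 was 2524-fold higher (1329 to 5520) in the library labelled day 6. CYP26A1, an enzyme that breaks down retinoic acid, was 532-fold higher (244 to 1451), and POU5F1 121-fold higher (94.3 to 157). ESRG, SHISA3, NPTX1, LINC00371, RP11-78L16.1, RP11-63A11.1 and RP11-568A7.4 were also among the named genes, between 117-fold (LINC00371) and 627-fold (SHISA3) higher. BMP4, a secreted signal, was 44.0-fold higher (37.0 to 52.7) in the library labelled day 0, NR2F2 30.3-fold (27.3 to 33.8) and the cell cycle inhibitor CDKN1A 13.5-fold (11.6 to 15.7). AC093590.1, ZNF503, FAM84B, ZNF385B, DLK1, DACH1 and AC068490.2 were the others, between 7.85-fold (DACH1) and 104-fold (AC093590.1); without the few cells that clustered with another library, DLK1 went from 9.96-fold to 17.0-fold and ZNF503 from 20.4-fold to 38.6-fold.

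**Figure D2:**
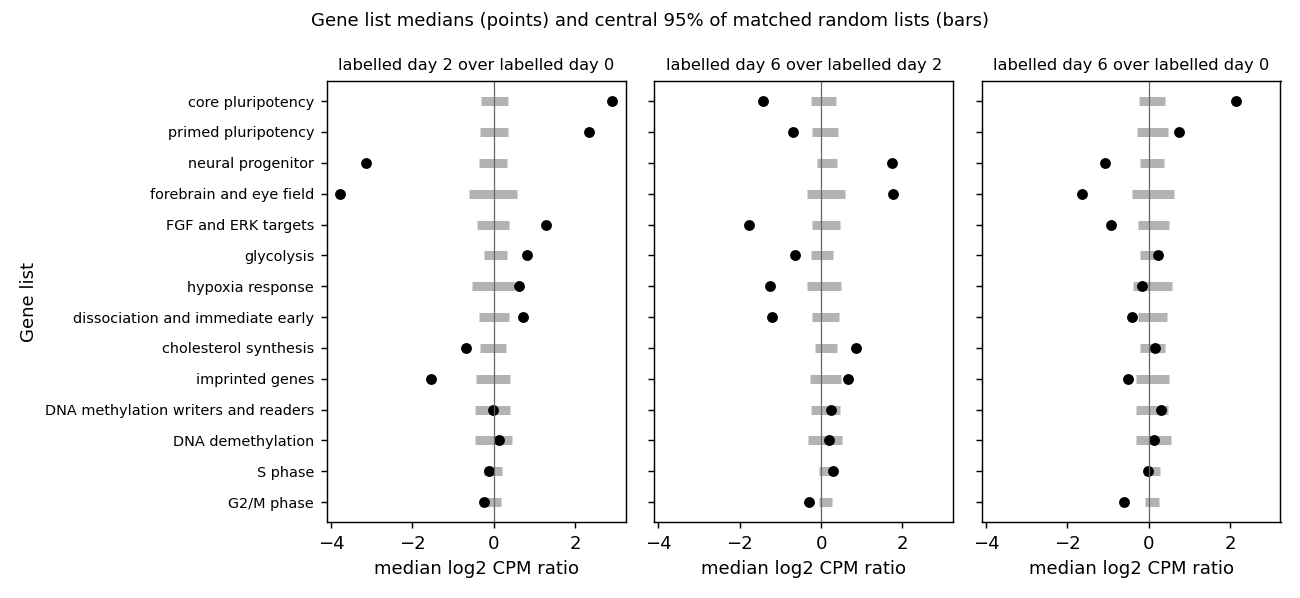
Median log2 CPM ratio (points) of 14 gene lists in each of the 3 comparisons between libraries, with the central 95% of 10000 random lists matched on mean CPM (grey bars). Core pluripotency lies at 2.91, -1.44 and 2.15, and neural progenitor at -3.13, 1.74 and -1.07.

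Because the series title concerns DNA methylation, its enzymes were compared across the libraries. DNMT3B, a de novo DNA methyltransferase on chromosome 20 at 32762385 to 32809356, stood at 70.6 CPM (67.6 to 73.8) in the library labelled day 0, 530.5 CPM (521 to 541) in that labelled day 2 and 601 CPM (593 to 608) in that labelled day 6. It was the member of 12 methylation writers and readers that was at least 2-fold higher in the libraries labelled day 2 and day 6 than in that labelled day 0. The other 11 lay between 0.5 and 2 times in each of these contrasts. For day 6 over day 2 the 1 member at least 2-fold higher was UHRF1, at 28.9, 19.7 and 50.3 CPM in the libraries labelled day 0, day 2 and day 6. DNMT1, which maintains methylation, stood at 124, 107 and 123 CPM, and DNMT3A at 38.1, 51.8 and 52.2 CPM. TET1, which oxidises methylated cytosine and lies on chromosome 10 at 68560656 to 68694482, stood at 147 CPM (142 to 151), 109 CPM (105 to 114) and 124 CPM (121 to 128). TET2 stood at 14.3, 3.88 and 8.58 CPM, and TET3 at 22.1, 31.7 and 53.5 CPM. Of 14 demethylation genes, 9, 11 and 9 lay between 0.5 and 2 times for day 2 over day 0, day 6 over day 2 and day 6 over day 0. Of 22 chromatin remodelling and histone modification genes, 20, 19 and 20 did; JARID2, a Polycomb partner, stood at 104, 411 and 230 CPM.

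Genes of epithelial and mesenchymal character differed in both directions. CDH1, the epithelial cadherin, stood at 1.13 CPM in the library labelled day 0, 94.2 CPM in that labelled day 2 and 39.7 CPM in that labelled day 6, whereas CDH2, the neural cadherin, stood at 446, 47.9 and 209 CPM. Of 15 members of this list, 7 were at least 2-fold higher and 7 at most 0.5 times in the library labelled day 2 against that labelled day 0. Among signalling targets, 7 of 14 FGF and ERK targets were at least 2-fold higher in the library labelled day 2 than in that labelled day 0 and 7 lay between 0.5 and 2 times, while 10 were at most 0.5 times in that labelled day 6 against that labelled day 2. FOS and EGR1 are also in the list of dissociation and immediate early genes, of which 7 of 17 were at least 2-fold higher and 10 at most 0.5 times in the same comparisons, so a stress of dissociation is not separated from signalling here. DUSP6, a phosphatase that dampens ERK, stood at 24.6, 125 and 4.56 CPM, and SPRY4 at 2.01, 52.3 and 3.37 CPM. In the BMP target list, ID1 stood at 87.3, 114 and 13.8 CPM, while 6, 5 and 4 of 7 members lay between 0.5 and 2 times in the 3 comparisons. Of 4 measured TGF-beta and Nodal targets, 3 were at least 2-fold higher in the library labelled day 2 than in that labelled day 0 and 4 were at most 0.5 times in that labelled day 6 against that labelled day 2. LEFTY1 had 2, 20 and 1 UMIs and NODAL 11, 17 and 47 UMIs, so little can be read from them at this depth.

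The position of the library labelled day 2 along the labelled course was examined for genes with at least 50 CPM. Of 103 genes at least 4-fold higher in the library labelled day 6 than in that labelled day 0, 73 had passed 50% of that log2 ratio in the library labelled day 2, and 42 lay beyond the level of the library labelled day 6. Of 46 genes at least 4-fold lower, 40 had passed 50% and 25 lay beyond. These counts follow the labelled order, and both ratios share the library labelled day 0, so they are not read as timing. Without an order, the middle value of genes with a 4-fold range lay in the library labelled day 0 for 19.5%, in that labelled day 2 for 24.6% and in that labelled day 6 for 55.9% of 297 genes. The library labelled day 2 was at least 2-fold above both others for 131 genes, led by LINC00678, TDGF1 and ANKRD31, and at most 0.5 times both others for 158 genes, among them GREB1L, SOX21, PAMR1, PRSS23 and the ephrin receptor gene EPHA4. With a mitochondrial limit of 10% the latter count was 309.

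Shares of cells with a UMI followed the same order when every cell was thinned to 1000 UMIs. POU5F1 was seen in 0.218% of cells (0.0709 to 0.509) of the library labelled day 0, 73.3% (71.5 to 75.05) of that labelled day 2 and 26.1% (24.8 to 27.5) of that labelled day 6. Without thinning these were 2.58%, 94.3% and 69.4%. PAX6 was seen in 17.9% (16.3 to 19.5), 0.413% (0.198 to 0.759) and 2.42% (1.97 to 2.93) of cells, and in 63.7%, 3.39% and 13.8% without thinning. Among 14 genes of tissues not in the culture the median share was 0, 0.0207 and 0%, and the highest, ACTA1, was 1.27%, 0.909% and 1.36%. In the library labelled day 6, ACTA1 went from 17.9 to 11.7 CPM without the 150 cells that clustered mostly with another library. It may thus be expressed in part of the culture and is not a sure background gene. Apart from ACTA1 the highest was 0.262% (MYH6) in the library labelled day 0 and 0.124% (PTPRC) in that labelled day 2. The thinned POU5F1 share of the library labelled day 0 is thus within this background. Without thinning its 2.58% lies above MYH6, at 1.57%, and below ACTA1, at 7.34%. The thinned PAX6 share of the library labelled day 2 is below ACTA1 and above the others. CUZD1 was seen in 0.0437%, 1.45% and 49.9% of cells. POU5F1 and PAX6 were seen together in 12 of 4180 cells of the library labelled day 6, against 26.4 for independent genes, and in 448 cells without thinning, against 399. The expected counts use shares of the whole library, which holds cells of differing content and, without thinning, of differing depth. Neither exclusion nor joint presence is therefore read from these counts.

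Clustering all kept cells gave 7 clusters, each with at least 90.7% of its cells from a single library, so clusters and libraries can hardly be separated. Clusters with pluripotency markers held 98.3% (97.7 to 98.7) of the cells of the library labelled day 2 and 1.12% (0.827 to 1.49) of that labelled day 6. Clusters with neural progenitor markers held 99.9% of the cells of the library labelled day 0, 36 cells or 1.49% (1.04 to 2.05) of that labelled day 2 and 103 cells or 2.46% (2.02 to 2.98) of that labelled day 6. The remaining 2 clusters, with 96.4% (95.8 to 97.0) of the cells labelled day 6, did not meet the marker rule and stay unnamed. The neural progenitor name was lost in all 3 libraries when cells were thinned to 1000 UMIs. With each library clustered alone, 0% of the cells labelled day 6 lay in clusters of either name, while 1.61% of those labelled day 2 lay in a neural progenitor cluster. Each library was also spread over clusters of low and of higher mitochondrial share.

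**Figure D3:**
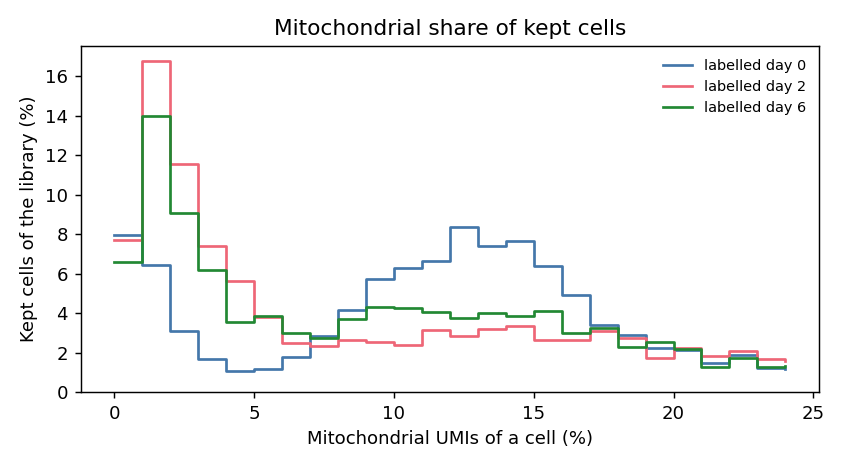
Share of kept cells (%) by the mitochondrial share of their UMIs (%) in steps of 1 percentage point, for the libraries labelled day 0, day 2 and day 6. Cells with under 5% mitochondrial UMIs made up 20.2%, 49.0% and 39.4% of the libraries.

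The summed level of the G2/M list was 6924 CPM in the library labelled day 0, 5593 CPM in that labelled day 2 and 4576 CPM in that labelled day 6, but most members lay between 0.5 and 2 times: 11 of 52 were at most 0.5 times in that labelled day 6 against that labelled day 0, 2 in that labelled day 6 against that labelled day 2 and 6 in that labelled day 2 against that labelled day 0. TOP2A stood at 468.5, 320 and 249.8 CPM and CENPF at 316, 143 and 142 CPM. The summed S phase list was at 3280, 3252 and 3574 CPM. Cells called G2/M made up 47.8% (45.7 to 49.8), 45.8% (43.8 to 47.9) and 31.3% (29.9 to 32.7). Without thinning the values of the libraries labelled day 0 and day 2 were 51.4% and 54.3%, so no order is read between them. Phase calls rest on relative scores that free RNA also enters.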

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

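The barcodes that the filter left out, 9001, 9904 and 11893 in the libraries labelled day 0, day 2 and day 6, enter no comparison above, yet they held UMIs of the markers above the limit that a count of 0 allows. POU5F1 stood at 2.00 CPM (0.917 to 3.80) in those of the library labelled day 0, 646 CPM (631 to 661) in those labelled day 2 and 199.6 CPM (191 to 208) in those labelled day 6. PAX6 stood at 187 CPM (174 to 199.7), 3.52 CPM (2.51 to 4.79) and 18.6 CPM (16.0 to 21.4) in the same order. The limits for a count of 0 were 0.668, 0.264 and 0.293 CPM. These values have the same order as those of the kept cells.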

How the results depend on the processing

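Restricting to cells with at least 5% mitochondrial UMIs, removing the highest 5% of doublet scores and leaving out cells in clusters mostly of another library were chosen after seeing the data. No paired analysis was possible because each day has 1 library. Of 16164 gene ratios under other settings 228 moved by over 1.5 times, 35 of them without cells in clusters mostly of another library, and 1 reversed, FOSB for labelled day 2 over day 0, at 0.906 with a mitochondrial limit of 10%. Of 1452 list medians 7 reversed: forebrain and eye field, day 6 over day 0, was 0.79 at a minimum of 50 CPM; midbrain and hindbrain, day 2 over day 0, was -0.20 with a mitochondrial limit of 10%, -0.22 with median-of-ratios factors and -0.31 with the mean of each cell's CPM; neural crest, day 2 over day 0, was -0.24 at 1 CPM; and mesoderm was 0.46 (day 2 over day 0) and 0.56 (day 6 over day 0) at 1 CPM. These lists have few measured members. A reversal was counted only where the main ratio, or the main median ratio of a list, was at least 2-fold in either direction. Changes of direction in smaller values are not counted as reversals. An example is ACTA1, day 6 over day 0, which went from 1.03 to 0.676 without cells in clusters mostly of another library. For the values below the cause was not tested, except that another threshold or depth changes a count by its construction. Counts of core pluripotency and neural progenitor members moved by over 1.5 times in these cases: pluripotency at most 0.5 times became 1 (day 2 over day 0, ratio of 1.5) and 2 (day 6 over day 0, mitochondrial limit of 10%); neural progenitor at least 2-fold became 2 (day 2 over day 0, 1 CPM), and at most 0.5 times 1 for day 6 over day 2 without the highest 5% of doublet scores, without cells in clusters mostly of another library, without mitochondrial and ribosomal protein genes, at 1 CPM and at a ratio of 1.5, and 7 for day 6 over day 0 at 50 CPM.

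Genes at least 4-fold higher in labelled day 6 than day 0 numbered 294 at 10 CPM, 55 at 100 CPM, 377 at a ratio of 2 and 62 at 8, and those past 50% 217, 43 and 222 at the first 3 of these. Genes 4-fold lower numbered 144 at 10 CPM, 223 at a ratio of 2 and 9 at 8, and those past 50% 121, 170 and 9. Genes higher in labelled day 2 than in both others numbered 443 at 10 CPM and 70 at 100 CPM, and those lower 366, 98 and, with a mitochondrial limit of 10%, 309. The middle value lay in labelled day 2 for 16.6% and in labelled day 6 for 63.0% of genes with the 10% limit, and in labelled day 6 for 49.7% at a ratio of 2. Named genes shared with the main choice were 6 of 10 (lower, day 6 over day 2, 10 CPM), 6 (higher, day 6 over day 0, 100 CPM), 5 and 6 (lower, day 6 over day 0, 10 and 100 CPM).

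The shares of cells depend on depth, on the UMIs asked for and on which cells are kept. Without thinning, POU5F1 was seen in 2.58%, 94.3% and 69.4% and PAX6 in 63.7%, 3.39% and 13.8% of cells labelled day 0, day 2 and day 6; among cells of at least 2000 UMIs thinned to 2000, which changes both the cells and the depth, in 0.540%, 90.7% and 42.9%, and 29.5%, 1.41% and 4.84%; with at least 2 UMIs, in 0%, 40.6% and 4.62%, and 2.36%, 0.0413% and 0.359%. Thinned to 500 UMIs, POU5F1 was at 50.8% (day 2) and 14.9% (day 6) and PAX6 at 8.52% (day 0) and 1.03% (day 6). With a mitochondrial limit of 10%, POU5F1 was at 79.9% (day 2) and 29.1% (day 6) and PAX6 at 0.197% (day 2); with at least 5% mitochondrial UMIs, POU5F1 at 66.2% (day 2) and 23.5% (day 6) and PAX6 at 3.002% (day 6). The order of the libraries for POU5F1 and PAX6 held in each of these settings.

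Pluripotent-like clusters held 95.9% (day 2) and 1.91% (day 6) when thinned, 97.0% and 0.632% with at least 5% mitochondrial UMIs, and 0% of day 6 with each library clustered alone. Neural progenitor-like clusters held 0% of all 3 libraries when thinned, where markers are seen in fewer cells by construction; 100%, 2.84% and 3.95% with at least 5% mitochondrial UMIs; and 100% (day 0) and 0% (day 6) with each library alone. G2/M shares were 51.4% (day 0) and 54.3% (day 2) without thinning, and 45.7% (day 0) and 26.4% (day 6) for cells of at least 2000 UMIs.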

Other observations

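Part of several metabolic and stress gene lists was higher in the library labelled day 2, while most members of the glycolysis, stress response, serine and cholesterol lists lay between 0.5 and 2 times. Glycolysis genes were at least 2-fold higher there than in the library labelled day 0 for 7 of 19 members, with LDHA at 203, 738 and 164 CPM in the libraries labelled day 0, day 2 and day 6. Of 11 hypoxia response genes, 5 were at least 2-fold higher in the library labelled day 2 than in that labelled day 0 and 7 at most 0.5 times in that labelled day 6 against it; BNIP3 stood at 64.8, 304 and 62.8 CPM. Of 17 dissociation and immediate early genes, 7 were at least 2-fold higher in the library labelled day 2 and 10 were at most 0.5 times in that labelled day 6 against it, with FOS at 29.04, 116 and 7.20 CPM. For the unfolded protein and integrated stress response these counts were 6 and 5 of 14, with the amino acid stress gene ASNS at 48.1, 184 and 52.0 CPM, and for serine and one-carbon metabolism 4 and 3 of 12. With a mitochondrial limit of 10% the median log2 ratio of the stress response list, day 6 over day 2, went from -0.64 to -0.26, and that of the dissociation list, day 2 over day 0, from 0.73 to 0.42. The library labelled day 2 also lost 1110 of 3529 barcodes to the mitochondrial limit, against 528 of 2818 and 990 of 5170 in those labelled day 0 and day 6, so a difference in the state of the cells when captured stays open. Nuclear oxidative phosphorylation genes lay between 0.5 and 2 times in all 3 comparisons (19 of 19). Some cholesterol synthesis genes went the other way: 6 of 19 were at most 0.5 times in the library labelled day 2 against that labelled day 0 and 8 at least 2-fold higher in that labelled day 6 against that labelled day 2, with HMGCS1 at 350 CPM, 102 CPM and 244 CPM.

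Of 11 measured imprinted genes 6 were at most 0.5 times and 4 between 0.5 and 2 times in the library labelled day 2 against that labelled day 0. The median log2 ratio was -1.55 (percentile 0). CDKN1C stood at 141, 43.1 and 99.8 CPM, and SNRPN, the member that was at least 2-fold higher, at 276, 763 and 455 CPM. Of 11 Notch pathway genes 6 were at most 0.5 times and 2, HEY2 and DLL3, at least 2-fold higher in the library labelled day 2 against that labelled day 0. The retinoid carrier CRABP1 stood at 281, 166 and 54.0 CPM. Of 6 measured neuronal genes 5 were at least 2-fold higher in the library labelled day 6 than in that labelled day 2, with DCX at 9.53, 6.74 and 59.85 CPM. For mesoderm and for endoderm 2 genes each reached 10 CPM.

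Every test of an explanation below was chosen after its result, or values close to it, had been seen. The first pattern is that marker content goes against the labels. Mixing of neural cells into a pluripotent library labelled day 0 is argued against by its cells in pluripotent-like clusters, 0.0437% of the kept cells. An exchange of only 2 labels that includes day 0 would place the library labelled day 0 or day 2 in the middle of most genes with a 4-fold range, if levels move in 1 direction with time, but the larger of these shares was 24.6% of 297 genes. A rotation of all 3 labels, with labelled day 2 first, labelled day 6 between and labelled day 0 last, may account for the pattern, since the library labelled day 6 held the middle value in 55.9% of these genes (49.7% with a 2-fold range). An exchange of the day 2 and day 6 labels gives the same middle. This exchange and a real course as labelled would both start from the library labelled day 0, and are argued against as courses from undifferentiated cells, since the core pluripotency genes had median log2 ratios of 2.91 and 2.15 in the libraries labelled day 2 and day 6 over that labelled day 0. A library of another culture stays open, because each day has 1 library. Only the library labelled day 2 has the letter B, which is not explained. A difference that goes with the letters could alter the shares of middle values and cannot be separated here.

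The second pattern is that every library held a class of cells with under 5% mitochondrial UMIs. Free RNA in droplets stays open. Barcodes under 500 UMIs had median mitochondrial shares of at least 18.9% in each library. They cannot decide this, since every barcode in the files had at least 100 genes and may hold a cell. At 2000 to 5000 UMIs, 2 nuclear RNAs were higher in the other cells than in this class. The ratios were 2.46, 2.59 and 1.26 for MALAT1 and 8.07, 16.9 and 3.97 for KCNQ1OT1 (labelled day 0, day 2 and day 6). Depth alone is argued against. Among cells of 2000 to 5000 UMIs, genes spanning over 100 kb lay below genes under 20 kb by at least 0.54 in each library. The gaps were -1.09, -0.54 and -0.62 on the log2 scale, in the same order. Over all kept cells the gap was -0.99, -1.14 and -0.85, so these cells also held less RNA of long genes; this does not explain their low mitochondrial share, which a loss of nuclear RNA alone would raise. What lowers it stays open. No biological explanation was tested, since the design gives no group within a library.

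The third pattern is the 36 cells labelled day 2 and 103 cells labelled day 6 in clusters mostly of the library labelled day 0. Those labelled day 6 depend on clustering the libraries together: with each library alone, 0% of the cells labelled day 6 lay in neural progenitor-like clusters, against 1.61% of those labelled day 2. With cells thinned to 1000 UMIs 0% of either did. This setting cannot decide the question, since the name was then lost for the library labelled day 0 as well, at 0%. Shared barcodes are argued against, since 7.91% of these cells share a barcode with the library labelled day 0. The shares were 9.38% and 10.6% of all kept cells labelled day 2 and day 6. Carry-over of a random set of cells labelled day 0 is argued against by 31 and 22 genes. These genes lay over 4-fold above the cells labelled day 0 in the same clusters. They had under 25% of this level in the rest of the own library. The highest of 20 random draws of cells labelled day 0 gave 4 and 1 genes over 4-fold, without the limit of 25%. The draws came from all clusters of that library together and held no difference between libraries. Carry-over of a particular part of its cells therefore stays open. Doublets with cells of the own library of like size would hold its genes at a sizeable level, but the median was 15.1% and 9.27% of that level. Doublets with smaller cells stay open: the median UMIs of these cells were 4338 and 7085, against 3811 and 4401 in the rest of their libraries, and no working doublet call was available. That these are differentiating cells of their own cultures may be considered, and was not tested beyond these values.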
